A study of Brassica napus with 16 samples.

How the data were processed

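RNA-seq was used to measure gene expression in 2 cultivars of Brassica napus (oilseed rape, an allotetraploid whose nuclear genome joins an A and a C subgenome), 2063A and B409. From each cultivar 4 tissues were sampled: young leaf, flower bud, silique and root. Each of the 8 cultivar-by-tissue groups has 2 replicates, giving 16 libraries, and the groups and replicate numbers were taken from the sample labels. Per the labels' protocols, roots were taken 7 d after planting on filter paper, young leaves from plants grown for 2 weeks in hydroponics, flower buds were no longer than 2 mm, and siliques were 3 to 5 cm long from field plants. Tissue is therefore tied to plant age and growing place in this design. The labels do not say that replicates came from separate plants, so the p-values measure the spread between these samples, which may be technical.

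Each library has its own deposited file with 1 FPKM value (fragments per kilobase of transcript, scaled to the number of mapped fragments) per gene, as the authors made it, per the file headers. The submitters' processing notes name Trimmomatic, TopHat2 and Cufflinks version 2.1.1, without their roles or settings. The genome build and annotation are not given in the sources used here. FPKM values are not counts, so count models were not used, and the read depth of each library is unknown, so no counting interval or floor was computed. Every file lists the same 101040 gene identifiers. Summed FPKM per library ran from 519039 to 617686.

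An exact 0 in FPKM files can be a failed estimate. Of 166707 cases in which a gene had an FPKM of 5 or more in at least 1 replicate of a group, the other replicate was listed at 0 in 38 (0.0228%). All 38 were in young leaf, 19 in each cultivar. Genes at 0 are described as listed at 0, and no fold change is stated where every library on 1 side of a comparison is listed at 0. Where some of these libraries are at 0, the log2 change depends on the pseudocount. How the authors assigned reads that match both an A and a C copy of a gene is not given in the sources used here, so values of near-identical homeologs are uncertain.

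Values were transformed to log2(FPKM + 1), and fold changes are on that scale, which understates the change of genes with low values. Genes with an FPKM of at least 1 in at least 2 libraries were tested (54206 genes). A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then empirical Bayes moderation with a mean-variance trend, 8 residual degrees of freedom, 3.35 prior degrees of freedom). All 16 libraries share 1 estimate of the spread of a gene. The contrasts were each tissue against the mean of the other 3 tissues, 2063A minus B409 in each tissue, and 2063A minus B409 averaged over the tissues. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 change of at least 1 (2-fold), two-sided. Dependence of the cultivar difference on tissue was tested with limma's moderated F over 3 interaction contrasts, at an adjusted p below 0.05. Every adjusted p given for a gene comes from these limma fits.

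On simulated values for 2063A against B409 in root, with 200 of 54206 genes changed, 64% of the genes changed 3-fold and 93% of those changed 8-fold were called in the simulated direction, and 7 unchanged genes were called. With root raised against the other tissues, 98% of the genes raised 3-fold and 100% of those raised 8-fold were called, and 0 unchanged genes were. The changed genes were drawn from tested genes above a minimum mean expression over the tissues, and a gene had the same simulated spread in every tissue. In the cultivar simulation genes at or near 0 in root could therefore be drawn, and multiplying such values changes them little or not at all. The shares called also do not cover tested genes with a lower mean or the larger spread of young leaf. The neighbour permutation test described next gave p = 0.934 for simulated scattered genes and p = 0.001 once a run of genes had been added, both with 54206 genes.

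The share of summed FPKM from A subgenome genes was compared between tissues with exact two-sided permutation tests of 4 against 4 libraries (6 pairs of tissues, Benjamini-Hochberg adjusted), and between cultivars with an exact two-sided permutation test that relabels libraries within tissues (1296 relabellings). Subgenome and chromosome were read from the identifiers, which give 44452 genes to the A and 56055 to the C subgenome and 533 to neither. Genes were ordered along chromosomes by identifier number. For the neighbour test, pairs of adjacent tested genes both called in the same direction in the cultivar contrast averaged over tissues were counted and compared, one-sided, with 100000 permutations of the calls within chromosomes. Fisher's exact test compared the share of called genes between the subgenomes (18 tests, Benjamini-Hochberg adjusted).

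No genome sequence was used here. The NCBI RefSeq gene table for assembly Da-Ae matched 3347 of the identifiers (3.31%), nearly all under the same identifier, and gave another name for only 2, so genes are printed as identifiers and no function is stated. Of 2939 matched genes on a named chromosome in both sources, 92.96% were on the same chromosome. The order of identifiers along the 19 chromosomes followed the RefSeq order with a median absolute Spearman rho of 0.862 across genes, which are not independent replicates (lowest 0.779). Coordinates were not used because the build of the files is not known. The gene lists for tissue functions that had been fixed in advance need gene products and were not tested.

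The rule for named genes, fixed before the data were examined, allows at most 2 rises and 2 falls per comparison when identifiers are not paired with names: the called genes with the largest log2 change whose libraries in the compared groups do not overlap. For the contrast averaged over tissues the libraries had to be separated in every tissue. For the interaction, the 2 genes with the smallest adjusted p are named. The alternatives fixed in advance were a pseudocount of 0.1, no filter on low values (71022 genes), equal totals per library, quantile normalization, a term for the replicate number, the omission of each library in turn, the 4 libraries of a tissue alone for the cultivar contrasts, and moderation without the trend. For the subgenome share they were leaving out the 100 most abundant genes, named chromosomes only, and the share of genes with an FPKM of at least 1. Library weights (limma's arrayWeights), a replicate term in young leaf alone, the search for chromosomal segments, the counts outside these segments, the relabelling of tissues within cultivars and the young leaf abundance filter with equal weights were added after seeing the data. Other analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.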

Results

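Expression was measured in 16 RNA-seq libraries of Brassica napus, from young leaf, flower bud, silique and root of the cultivars 2063A and B409, with 2 replicates in each of 8 groups. The files give FPKM per gene and no counts, so the depth of the libraries is unknown. Between 33483 and 41456 genes per library had an FPKM of at least 1. Young leaf had the fewest, with 34670 ± 1033 genes (SD, n = 4), compared with 40334 ± 1272 in flower bud, 39667 ± 773 in silique and 38823 ± 278 in root (n = 4 each). The 100 most abundant genes of a library held 25.8% ± 1.30 of summed FPKM in young leaf (SD, n = 4), 12.3% ± 0.28 in silique, 9.38% ± 0.81 in flower bud and 9.35% ± 0.33 in root. Across genes, log2 values of replicates correlated at r = 0.986 to 0.990 in flower bud, silique and root, and at 0.955 (2063A) and 0.948 (B409) in young leaf. Between the cultivars r was 0.874 to 0.916 within a tissue, and between root and the other tissues of a cultivar it was 0.426 to 0.539. Genes are not independent replicates, so these values describe similarity only.

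Of the 101040 listed genes, 21344 (21.1%) had an FPKM of at least 1 in every library and 44231 (43.8%) were below 1 in every library. Expression at an FPKM of at least 1 in the 4 libraries of a tissue and below 1 in the other 12 was found for 2649 genes in root, 1039 in flower bud, 669 in silique and 284 in young leaf.

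The first comparison asked which genes each tissue expressed above or below the mean of the other 3, so a called gene need not lie beyond each of them. All 4 libraries of the tissue lay beyond all 12 others for 8253 of the 10131 genes called higher in root and 5093 of the 8080 lower. In flower bud this held for 5043 of 7642 higher and 1133 of 5033 lower genes, in silique for 2069 of 5061 and 295 of 3040, and in young leaf for 3155 of 5263 and 4880 of 11122. For a gene that was not selected, chance puts 4 given libraries beyond the other 12 in a given direction in 0.0549% of arrangements. The genes counted here were called on the same libraries, so that rate is no benchmark for them. The named genes come from those without overlap. In root, 10131 genes were called higher and 8080 lower. Among the genes higher in root, BnaC01g15480D reached an FPKM of 2360 ± 185 (SD, n = 4), while the 12 other libraries lay between 0.48 and 17.4 (log2 change 9.16, SE 0.14, adjusted p = 7.9e-14). BnaA03g30810D was at 664 ± 121 in root (SD, n = 4), and 11 of the 12 other libraries listed it at 0 (log2 change 9.35, SE 0.06, adjusted p = 1.4e-15). The pair with the deepest falls in root lay on chromosomes C04 and A04. BnaC04g30870D did not exceed 0.872 in any root library and ranged from 1020 to 8590 elsewhere (log2 change -11.21, SE 0.11, adjusted p = 3.4e-15). BnaA04g20150D did not exceed 0.703 in root and ranged from 644 to 9320 elsewhere (log2 change -10.72, SE 0.10, adjusted p = 2.1e-15). Both were listed at 0 in the 2 root libraries of B409.

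In flower bud, 7642 genes were called higher and 5033 lower. BnaA10g23670D had an FPKM of 1410 ± 146 in flower bud (SD, n = 4) and was listed at 0 in the 12 other libraries (adjusted p = 5.6e-16). BnaA03g12750D was also listed at 0 in those 12 libraries, and in flower bud it was at 580 ± 31.1 in 2063A and at 2500 ± 196 in B409 (SD, n = 2 each; adjusted p = 5.6e-16 for the tissue). The genes with the deepest falls in flower bud were BnaC06g28720D and BnaC06g28740D, which have nearby identifier numbers on chromosome C06. BnaC06g28740D ranged from 0.489 to 3.79 in flower bud and from 6.02 to 1340 elsewhere (log2 change -5.41, SE 0.17, adjusted p = 1.3e-10). BnaC06g28720D did not exceed 1.95 in flower bud and ranged from 3.93 to 1900 elsewhere (log2 change -5.51, SE 0.31, adjusted p = 2.3e-08). The call count leaned to higher genes, which made up 60.3% of calls with FPKM as deposited and 46.2% after quantile normalization (5328 higher, 6205 lower). The median change of all tested genes in flower bud was 0.21 on the log2 scale as deposited and 0 after quantile normalization.

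In silique, 5061 genes were called higher and 3040 lower. BnaA05g18870D had an FPKM of 497 ± 126 in silique (SD, n = 4) and was listed at 0 in all 12 other libraries (adjusted p = 1.0e-14). BnaA05g20420D was at 430 ± 54.4 (SD, n = 4) and did not exceed 0.177 elsewhere (log2 change 8.70, SE 0.08, adjusted p = 1.3e-14). Both carry A05 identifiers. BnaC04g36290D did not exceed 0.266 in silique and ranged from 2.29 to 141 elsewhere (log2 change -4.37, SE 0.11, adjusted p = 2.7e-11). BnaCnng37610D, which carries no chromosome, was between 1.04 and 3.08 in silique and between 12.9 and 371 elsewhere (log2 change -4.34, SE 0.19, adjusted p = 2.3e-09).

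In young leaf, 5263 genes were called higher and 11122 lower. BnaC05g01450D ranged from 209 to 1040 in young leaf and did not exceed 5.87 in the other libraries (log2 change 8.37, SE 0.22, adjusted p = 3.5e-11). BnaC04g19890D ranged from 147 to 442 and did not exceed 2.31 elsewhere (log2 change 7.84, SE 0.11, adjusted p = 9.6e-13). Among the lower genes, BnaCnng14300D was between 5.72 and 14.8 in young leaf and between 265 and 888 elsewhere (log2 change -5.71, SE 0.13, adjusted p = 9.1e-12). BnaAnng37980D was between 2.96 and 17.7 in young leaf and between 77.8 and 2680 elsewhere (log2 change -5.69, SE 0.16, adjusted p = 4.5e-11). The lean to lower genes depended on the scaling. Higher genes made up 32.1% of calls as deposited and 55.9% after quantile normalization, which called 7290 higher and 5750 lower. The median change of all tested genes in young leaf was -0.51 as deposited, -0.58 with equal totals and -0.18 after quantile normalization, and counts of changes are relative to this shift.

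**Figure D1:**
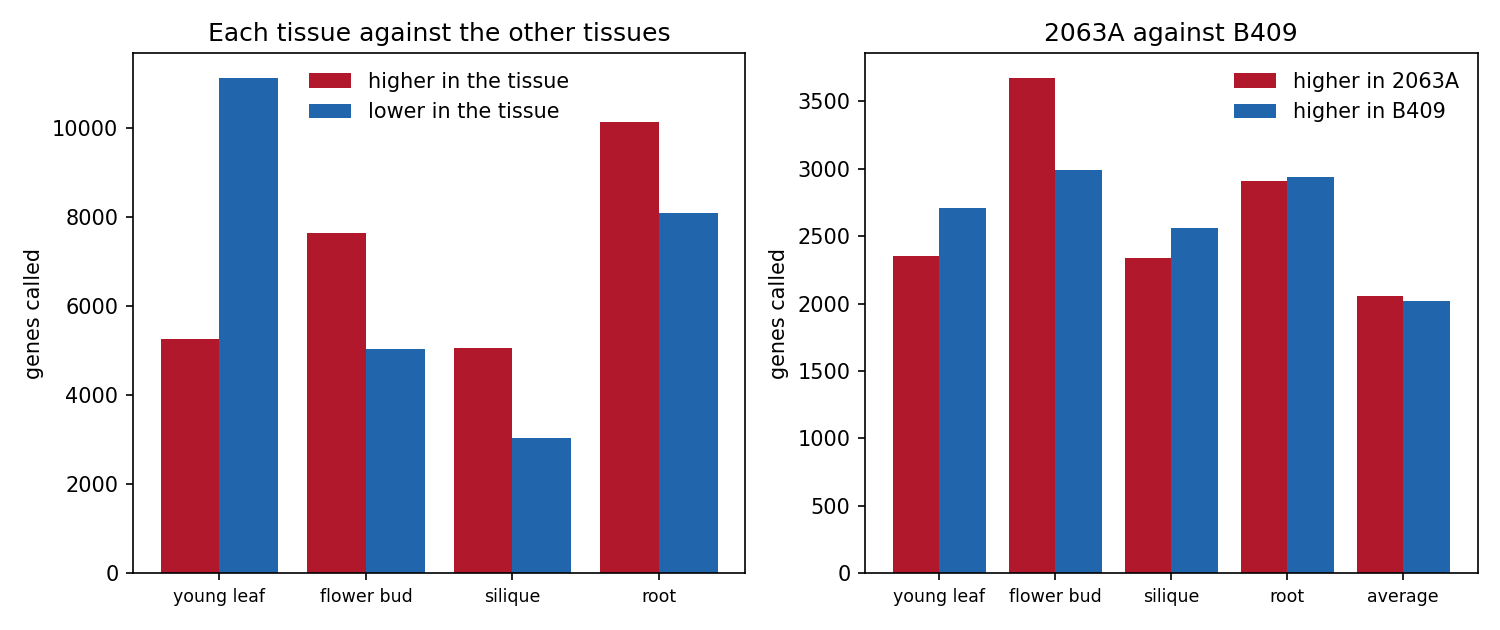
Number of genes called by limma (adjusted p below 0.05 and at least 2-fold, FPKM as deposited) for each tissue against the other tissues (left) and for 2063A against B409 in each tissue and averaged over tissues (right). Bars show higher and lower genes separately. Root has 10131 higher and 8080 lower genes, and young leaf has 5263 higher and 11122 lower.

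The second comparison set 2063A against B409. Averaged over the 4 tissues, 2056 genes were called higher in 2063A and 2017 higher in B409. BnaCnng01440D was at 61.2 to 208 in the 8 libraries of 2063A and did not exceed 0.117 in B409 (log2 change 6.67, SE 0.06, adjusted p = 6.0e-14). BnaC09g00220D reached 1420 ± 214 in young leaf of 2063A against 3.29 ± 2.16 in B409 (SD, n = 2 each), and 461 ± 38.7 against 1.32 ± 0.48 in silique (log2 change over tissues 6.39, SE 0.17, adjusted p = 1.1e-10). On the side of B409, BnaA06g28610D was at 29.1 to 138 and did not exceed 1.87 in 2063A (log2 change -5.52, SE 0.12, adjusted p = 1.5e-11). BnaC05g00290D was at 24.9 to 44.7 in B409 and did not exceed 0.823 in 2063A (log2 change -4.88, SE 0.08, adjusted p = 2.7e-12). At the extreme, 97 genes had an FPKM of at least 1 in all 8 libraries of 2063A and were listed at 0 in all 8 of B409, and 39 genes showed the opposite arrangement. A pseudocount of 0.1 raised the counts over tissues to 4376 and 3960.

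In flower bud, 3673 genes were called higher in 2063A and 2991 in B409, and after quantile normalization 2875 and 3463. BnaA10g21870D was at 124 ± 12.9 in flower bud of 2063A (SD, n = 2) and listed at 0 in both flower bud libraries of B409 (adjusted p = 1.6e-10). BnaA09g54870D was at 256 ± 24.8 in 2063A (SD, n = 2) and also listed at 0 in B409 (adjusted p = 7.0e-10). BnaC03g23520D was at 105 ± 7.22 in B409 and 0.278 ± 0.009 in 2063A (SD, n = 2 each; log2 change -6.37, SE 0.29, adjusted p = 2.8e-08). BnaA06g28610D was at 128 ± 14.3 in B409 and 1.40 ± 0.66 in 2063A (SD, n = 2 each; log2 change -5.77, SE 0.23, adjusted p = 1.1e-08). In root the counts were 2906 and 2941. BnaCnng01440D, at 138 ± 2.42 in root of 2063A (SD, n = 2), was listed at 0 in root of B409 (adjusted p = 2.8e-11), and BnaC03g03750D was at 119 ± 1.87 against 0.029 ± 0.041 (SD, n = 2 each; log2 change 6.87, SE 0.22, adjusted p = 1.2e-09). BnaA01g33660D was at 287 ± 5.88 in root of B409 and 0.508 ± 0.076 in 2063A (SD, n = 2 each; log2 change -7.58, SE 0.15, adjusted p = 6.1e-11). BnaA04g29060D was at 84.7 ± 10.3 in root of B409 (SD, n = 2) and listed at 0 in 2063A (adjusted p = 4.4e-08).

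In silique, 2339 genes were called higher in 2063A and 2560 in B409. BnaA09g54870D was at 375 ± 11.4 and BnaA10g05680D at 295 ± 0.36 in silique of 2063A (SD, n = 2 each), and both were listed at 0 in silique of B409 (adjusted p = 2.4e-10 and 5.4e-11). BnaAnng04290D was at 145 ± 24.5 in B409 and 0.099 ± 0.14 in 2063A (SD, n = 2 each; log2 change -7.05, SE 0.19, adjusted p = 5.6e-10). BnaA03g28370D was at 121 ± 37.7 in B409 and 0.181 ± 0.256 in 2063A (SD, n = 2 each; log2 change -6.67, SE 0.31, adjusted p = 4.7e-08).

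In young leaf, 2349 genes were called higher in 2063A and 2708 in B409. BnaA09g54870D was at 2170 ± 744 and BnaA10g05680D at 692 ± 59.2 in young leaf of 2063A (SD, n = 2 each), BnaA10g05680D was listed at 0 in young leaf of B409, and BnaA09g54870D did not exceed 0.131 there (adjusted p = 7.4e-11 for BnaA09g54870D and 4.5e-11 for BnaA10g05680D). BnaA03g28370D was at 184 ± 87.4 in B409 and 0.440 ± 0.422 in 2063A (SD, n = 2 each; log2 change -6.95, SE 0.31, adjusted p = 5.6e-08). BnaC02g37040D was at 1470 and 1940 in the libraries of B409 and at 1.11 and 139 in those of 2063A (log2 change -6.62, SE 1.28, adjusted p = 0.0032). These calls rest on a spread pooled over the tissues, which understates the spread in young leaf, where the median residual SD was 0.244 against 0.114 to 0.133 in the other tissues. When limma was fitted to the 4 young leaf libraries alone, 0 genes were called (smallest adjusted p = 0.051), and 1883 genes higher in 2063A and 2298 higher in B409 had an unadjusted p under 0.05 with at least a 2-fold change. Without B409 young leaf replicate 1 the counts were 3586 higher in 2063A and 2964 in B409.

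The cultivar differences were shared between tissues more than independent lists would be. In flower bud and silique, 1617 genes were higher in 2063A in both, against 158.5 for independent lists, and 1391 genes were higher in B409 in both, against 141.3. Independent lists are a low benchmark, because the same spread of a gene serves every tissue. All tested genes also enter it, with those too low in a tissue to be called there. Some excess was therefore built in, and its size is not a measure of shared regulation. A total of 849 genes were higher in 2063A in all 4 tissues and 733 higher in B409 in all 4, while 152 genes were called in opposite directions in different tissues. The cultivar difference depended on tissue for 11306 genes by the interaction test. Of these, 4834 were called between the cultivars in exactly 1 tissue (1872 in flower bud, 1539 in root, 785 in young leaf and 638 in silique), 3842 in no tissue, 529 in all 4 tissues in 1 direction and 152 in opposite directions. BnaA09g44670D had the smallest interaction p (adjusted p = 5.7e-10). It was at 78.9 ± 1.81 in silique of B409 (SD, n = 2) and was listed at 0 in the other 14 libraries. BnaA04g14140D followed (adjusted p = 1.3e-09), at 37.5 ± 3.37 in young leaf of 2063A (SD, n = 2), not above 0.116 in silique of 2063A and listed at 0 in young leaf of B409.

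The third comparison concerned the subgenomes. The A subgenome contributed 50.07% of summed FPKM on average over the 16 libraries. The files list fewer A genes (44452) than C genes (56055), but A genes made up 49.04% of the genes with an FPKM of at least 1. The median FPKM of such genes, averaged over the libraries, was 5.0 for A and 5.16 for C. Without the 100 genes with the highest mean FPKM, the A subgenome contributed 49.11% of summed FPKM. The A subgenome share of summed FPKM was higher in 2063A than in B409, at 50.59% against 49.56% averaged over the tissues, a difference of 1.03 percentage points (exact permutation test within tissues, two-sided p = 0.00463 over 1296 relabellings). The mean of 2063A was above that of B409 in all 4 tissues, although in silique the libraries of the cultivars overlapped (49.63% and 49.66% in 2063A, 49.53% and 49.69% in B409). The highest value was 53.74%, in young leaf replicate 1 of 2063A. Without that library the difference was 0.74. Without the 100 genes with the highest mean FPKM over all libraries it was 0.73 (exact permutation test, p = 0.017), and the mean of 2063A was higher in 3 of the 4 tissues. With named chromosomes only it was 0.97 (exact permutation test, p = 0.00617), again with 2063A higher in 3 of the 4 tissues. In the share of genes with an FPKM of at least 1 it was 0.31 (exact permutation test, p = 0.00617). Between tissues, the share was 51.32% in young leaf, 50.09% in flower bud, 49.63% in silique and 49.25% in root, and no pair of tissues passed after adjustment (exact permutation tests, smallest adjusted p = 0.0857 over 6 pairs, with 0.0286 the smallest unadjusted p the design allows). These tests leave the cultivar difference in the spread. With libraries relabelled within each cultivar, a test added after seeing the data, 5 of the 6 pairs reached the smallest p that 36 relabellings allow (exact permutation test, two-sided p = 0.0556), and their libraries did not overlap in either cultivar. The exception was flower bud against silique (exact permutation p = 0.222), and this test cannot reach 0.05 for any pair.

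**Figure D2:**
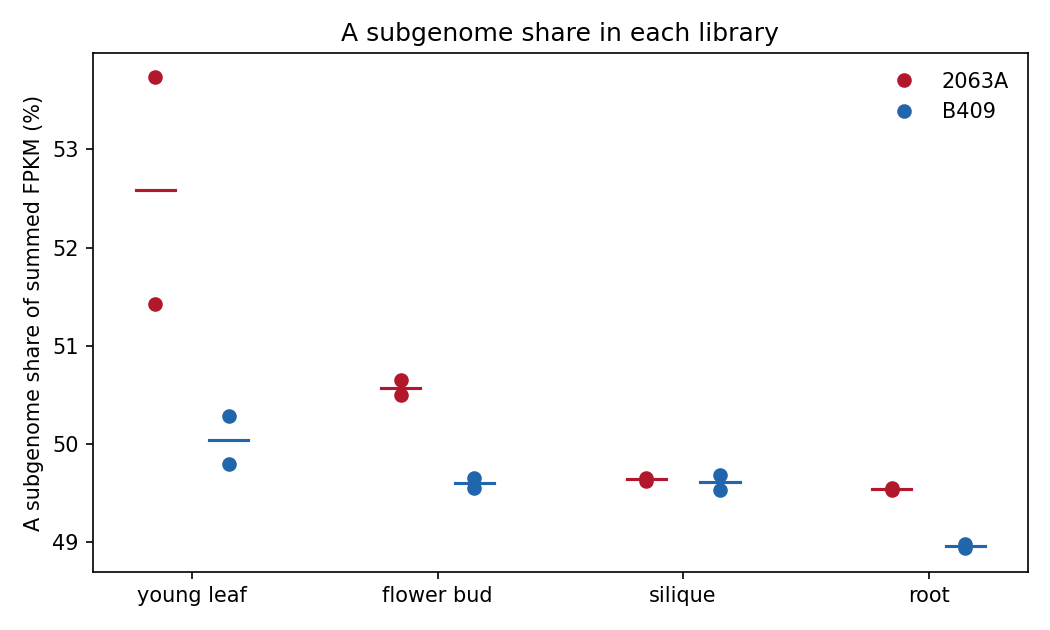
A subgenome share of summed FPKM (%) in each library by tissue. Points are single libraries (2 per group), short lines are group means, and the axis does not start at 0. The young leaf libraries of 2063A, at 53.74% and 51.43%, lie above those of B409, at 50.29% and 49.80%.

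Genes of the A subgenome were called higher in 2063A more often than genes of the C subgenome, at 4.61% of 26678 tested A genes and 2.99% of 27387 tested C genes over the tissues (Fisher's exact test, odds ratio 1.57, adjusted p = 1.9e-22). For genes higher in B409 the shares were 3.73% and 3.71% (odds ratio 1.0, adjusted p = 0.95), but single tissues lay on either side, and their difference was not tested. In silique 5.43% of A and 4.02% of C genes were higher in B409 (odds ratio 1.37, adjusted p = 2.5e-14), and in young leaf 4.71% and 5.28% (odds ratio 0.89, adjusted p = 0.0044). Neighbouring genes count as separate genes in this test. The even shares for B409 over the tissues depended on C02 and C09, where 275 of 1962 and 195 of 2723 tested genes were higher in B409. The other named C chromosomes had 1.2% to 3.0% and the A chromosomes 1.6% to 5.7%. Among genes without a chromosome the shares were 4.3% for C and 4.5% for A. The excess of A genes may therefore not be particular to genes higher in 2063A, which was not tested.

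The last planned comparison asked whether called genes lie side by side. On the named chromosomes, 836 pairs of adjacent tested genes were called in the same direction between the cultivars, against 181.1 expected and at most 236 in 100000 permutations within chromosomes (one-sided p = 1e-05, the smallest they can give). The excess was present in each tissue, with ratios of observed to expected pairs of 3.40 in young leaf, 2.80 in flower bud, 3.82 in silique and 3.39 in root. By chromosome, the share of genes higher in 2063A was highest on A10 (10.7% of 1976 tested genes), and the share higher in B409 on C02 (275 of 1962).

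**Figure D3:**
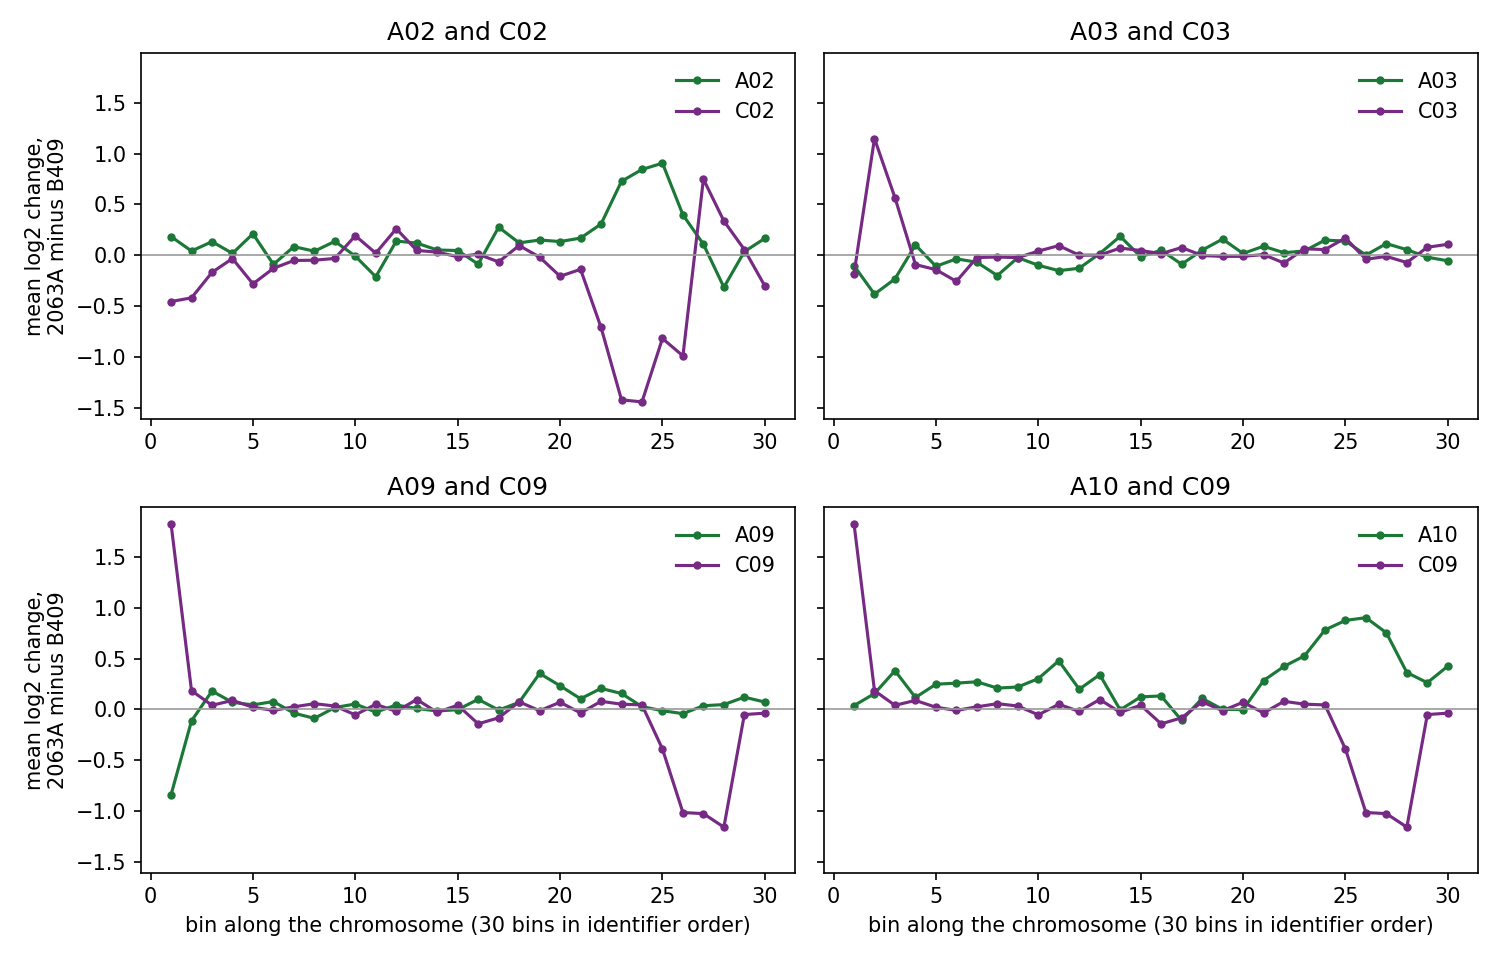
Mean log2 change between the cultivars (2063A minus B409, averaged over tissues) in 30 bins of tested genes along A02 and C02, A03 and C03, A09 and C09, and A10 and C09, in identifier order. Joined points are bin means without error bars, the chromosome pairs were chosen after the results were seen, and in bins 22 to 26 A02 lies above 0 and C02 below it.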

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

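The split counts, and the choice of measures screened for single outlying libraries, were made after the results were seen. The interaction test was planned.

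The A subgenome share of summed FPKM in young leaf replicate 1 of 2063A, at 53.74%, stood apart from the other 7 libraries of 2063A, with a gap to the nearest of 0.550 of the range of all 8. It was the only library to do so among 24 screens of 4 library measures, and chance marks about 1 group in 20.

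The difference between the cultivars depended on tissue for 11306 of 54206 genes (limma's moderated F test). The test uses the spread pooled over the tissues, which understates that of young leaf. BnaA09g44670D (adjusted p = 5.7e-10) was expressed in silique of B409 and listed at 0 elsewhere, and BnaA04g14140D (adjusted p = 1.3e-09) was above 1 FPKM in young leaf of 2063A alone.

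Among 100 splits of the libraries, the real one gave the most genes for young leaf, flower bud and root and for genes higher in silique. For genes lower in silique another split gave more. A split that mixes the real groups puts their differences into the spread. The median of the other splits was accordingly 0 genes for each tissue count and 8 for the cultivar counts. The real split was thus likely to rank first, so the ranking cannot exclude chance. For young leaf, 1 of 100 splits (the real one) gave as many higher genes (5263, highest other 4805) and 1 gave as many lower genes (11122, highest other 3629). The number was 1 of 100 for flower bud, in both directions (7642, highest other 3203, and 5033, highest other 2296), for genes higher in silique (5061, highest other 4552) and for root in both directions (10131, highest other 2189, and 8080, highest other 526). For genes lower in silique, 2 of 100 splits gave as many, with 3040 for the real split and 3315 for the highest other. Over tissues, 1 of 100 splits gave as many genes higher in 2063A (2056, highest other 1149) and 1 gave as many higher in B409 (2017, highest other 1149).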

How the results depend on the processing

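The library weights, the replicate term in young leaf alone and the counts outside chromosomal segments were chosen after seeing the data, and the other alternatives were planned. Under the alternatives, 491 counts and shares stayed within a wide bound of the value reported, 16 moved beyond it, and no named gene reversed direction. Counts within that bound still changed in size. With a pseudocount of 0.1, genes higher in B409 in young leaf went from 2708 to 3998, and genes higher in 2063A in root from 2906 to 4239. The lean of the calls did turn round under quantile normalization, to 7290 higher and 5750 lower in young leaf, 5328 higher and 6205 lower in flower bud, and 2875 higher in 2063A and 3463 in B409 in flower bud. The near-even cultivar counts turned round in root with a pseudocount of 0.1 (4239 and 3821), and over tissues with equal totals (2024 and 2047) and quantile normalization (1916 and 2158). Leaving out 1 library turned them round in young leaf without replicate 1 of 2063A (2909 and 2672) or of B409 (3586 and 2964), in silique without replicate 1 of 2063A (2259 and 2165), in root without replicate 1 of B409 (2855 and 2760), and over tissues without 2063A young leaf replicate 2 (2032 and 2093), 2063A silique replicate 2 (2009 and 2078) or B409 flower bud replicate 2 (2030 and 2066). With a pseudocount of 0.1, which weights low values more, the counts were 21975 lower in young leaf, 13913 higher and 9891 lower in flower bud, 9069 higher and 7553 lower in silique, 13217 lower in root, 3935 higher in 2063A in young leaf, 5567 higher in 2063A in flower bud, 4376 and 3960 higher in 2063A and B409 over tissues, and 2100 neighbouring pairs (at most 737 in 100 permutations). Counting called genes within 5 tested genes gave 1623 neighbouring pairs, a wider definition by construction. With the 4 libraries of the tissue alone, 0 genes were called higher in 2063A and 0 higher in B409 in young leaf, and the 4 calls of named genes there ended (adjusted p = 0.051, 0.051, 0.067 and 0.40); the spread within young leaf was larger than in the other tissues. Apart from these, the cause was not tested. Omitting single libraries, where the lone replicate is assumed to vary like the other groups, gave 2257 to 3586 genes higher in 2063A in young leaf, the highest without B409 young leaf replicate 1, and 8904 to 14794 interaction genes. The named genes otherwise kept direction and call, in 804 combinations of a named gene, its comparison and a refit. Library weights gave 1788 and 2156 genes in young leaf, where libraries weighed 0.359 to 0.383 against 1.18 to 1.62 elsewhere. Outside the segments, 1748 genes were higher in 2063A and 1496 in B409 over tissues.

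The replicate numbers did not pair the libraries across groups in general, and the exception was the young leaf pair of groups: deviations of same-numbered libraries correlated at -0.175 to 0.335 over 28 pairs of groups (median 0.007, 1 above 0.1, between the young leaf groups). With the replicate block the counts over tissues were 2056 and 2017, with 10849 interaction genes and 838 neighbouring pairs. With a replicate block in young leaf alone, and the spread pooled over tissues, 2498 genes were higher in 2063A and 2791 in B409 in young leaf. Gene list tests were not run, because gene products were not used here. The depth is unknown, so its limits were not computed.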

Other observations

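The neighbour permutation test was planned. The segment search, the comparison of A and C chromosomes with its tests, the young leaf split tests, the overlap of segments with calls in all tissues, and the comparison of the young leaf pair of groups with the other pairs were chosen after the results were seen. The bounds for the quantile and abundance tests of replicate deviations and for tissue-wise neighbours were written before those values were seen.

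The neighbouring cultivar differences gathered into 22 segments (12 higher in 2063A, 10 higher in B409) on 12 chromosomes, where at most 2 arose in 100 permutations. They hold 1332 tested genes (2.46%) and 818 genes called in the segment's direction, which is 20.1% of the 4073 called genes. Another penalty for uncalled genes gave 25 or 23 segments. At the start of C09, 53 of 63 genes from BnaC09g00010D to BnaC09g01040D were higher in 2063A, and among the 36 with an FPKM of at least 5 in 2063A the median gene kept 0.3% of that value in B409. At the start of A09, 40 of 85 genes from BnaA09g00670D to BnaA09g01770D were higher in B409. The median of the 53 with an FPKM of at least 5 in B409 kept 34.4% in 2063A. The medians that follow also cover only genes with an FPKM of at least 5 in the higher cultivar. These are 57 genes on C03, 112 on C02, 18 on A02, 136 on C09 and 56 on A10. Choosing genes by the higher side lowers the share kept. From BnaC03g02750D to BnaC03g05740D, 98 of 148 genes were higher in 2063A and the median kept 1.5% in B409. On C02, 170 of 291 genes from BnaC02g34860D to BnaC02g42120D were higher in B409 (median 16.6% kept in 2063A), and on A02, 24 of 29 genes from BnaA02g28540D to BnaA02g28950D were higher in 2063A (median 26.6% kept in B409). On C09, 165 of 307 genes from BnaC09g45880D to BnaC09g50830D were higher in B409 (median 36.1% kept in 2063A), and on A10, 40 of 77 genes from BnaA10g25310D to BnaA10g26380D were higher in 2063A (median 40.6% kept in B409). The C09 segment varied by tissue, with a median log2 change of -1.82 in root, -1.48 in young leaf, -0.64 in flower bud and -0.28 in silique. The segment on A01 (35 of 45 genes) and those on C01 (18 of 24 and 8 of 11) were all higher in B409, so this pair did not mirror in its segments. Among the genes named for the cultivars, BnaC09g00220D, BnaC03g03750D, BnaA01g33660D and BnaC02g37040D lie inside segments of C09, C03, A01 and C02. Their differences are therefore not isolated from those of their neighbours.

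Several segments mirror each other on A and C chromosomes, but not all do. No segment was found on A03 opposite the one on C03. The segments on C02 that start at BnaC02g43080D and BnaC02g45020D were higher in 2063A, and no segment on A02 was higher in B409. A chance order of called genes is excluded by the neighbour permutations (p = 1e-05, the smallest they can give). Loss or poor mapping of single segments as the whole cause predicts no change in the partner, but the bins of A01 and C01, A02 and C02, A03 and C03 gave a mean r of -0.63, and no other of 27000 circular shifts was as low (share 3.7e-05, the smallest they can give); without the bin with the largest changes, r was -0.73 for A02 and C02, but -0.20 for A03 and C03 and -0.09 for A01 and C01, so the argument holds mainly for A02 and C02, and the r of A01 and C01 rests on 1 bin. An exchange between homeologous segments in 1 cultivar may account for the mirrored segments, as a hypothesis. Its only test was the same share of shifts (3.7e-05) used above for the loss of single segments. That share therefore gives an exchange no support of its own. Reads of a diverged segment assigned to the homeologous copy would mirror too and cannot be told apart from an exchange without reads. The median FPKM kept in the lower cultivar was 24.0% over 618 segment genes with an FPKM of at least 5 in the higher.

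Among genes called in the average over tissues, from which the segments were built, 23.4% of the 1582 called in all 4 tissues lay in the segments, against 18.4% of the 2491 others (Fisher's exact test, odds ratio 1.35, p = 0.00015). Genes of a segment are not independent, so this p overstates the evidence. Genes higher in a tissue also lay side by side more than in any of 1000 permutations in each tissue, by ratios from 1.18 (flower bud) to 1.44 (silique).

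More genes were lower than higher in young leaf, with 32.1% of calls higher. A few abundant genes taking the total does not account for the whole split, since scaling to the total outside 398 abundant genes left 38.3% higher. Low values near the detection limit stay open for the split of calls but are argued against for the shift of all genes, since 45.3% of calls were higher (2683 higher, 3241 lower) and the median log2 change was still -0.52, against -0.51 over all tested genes, among 10825 genes with a mean FPKM of at least 10 when young leaf and the other tissues weigh equally (34.9% with the mean of all 16 libraries, which admits genes low in young leaf more easily and decides nothing). A different distribution of values in young leaf also stays open and cannot be told apart from a biological shift, because quantile normalization (55.9% higher) removes both. Tissue also differs in plant age and growing place, which was not tested.

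Young leaf libraries of the same number deviated together in both cultivars, with r = 0.335 across genes, against -0.175 to 0.049 in 27 other pairs of groups, where both values beyond 0.1 in size joined flower bud of 2063A with young leaf (-0.175 for B409, -0.125 for 2063A). Library scale is argued against by r = 0.315 after quantile normalization, and noise of low genes by r = 0.41 among genes with a mean FPKM of at least 10. Replicate 1 was more than 2-fold lower in both cultivars for 355 genes and more than 2-fold higher for 206, against 56.0 and 37.0 for independent deviations. A day, batch or plant stage shared by libraries of the same number may account for this, as a hypothesis (r = 0.335); the labels name none.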
